A study of Mus musculus with 4 samples.

How the data were processed

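Messenger RNA was measured in 4 libraries of E14TG2a mouse ES cells, 2 from control and 2 from KAT6A knockout cells. Per the labels' protocols, RNA was extracted on columns with DNase digestion, and libraries were made with the TruSeq Stranded mRNA kit, which selects polyadenylated RNA and keeps strand. Groups and replicate numbers were taken from the sample titles. The deposited per-library tables hold whole-number read counts per gene symbol, and the submitters' processing notes name featureCounts and DESeq2 without versions. The aligner, genome build, annotation and strand setting are not given in the sources used here, so overlapping and antisense genes cannot be told apart with certainty. A deposited table of normalized counts, a signal per gene and library, was compared with the counts: the authors had divided each library by a single factor (1.11, 1.15, 0.945 and 0.848 in the order control 1, control 2, KO 1, KO 2). The authors also deposited the results of their own comparison. Its columns were identified from their values and order, since the deposited table has no header: the mean normalized count (signal), the log2 fold change, its standard error, a Wald statistic (score), the p-value and the adjusted p-value.

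Libraries held 27494041 to 37354623 counts. Replicates were checked for duplication with a chi-square statistic per gene with at least 20 pooled counts. Its mean was 3.70 between the controls and 34.4 between the KO libraries, so both pairs differed by more than sampling noise and each library was counted separately. Intervals cover counting error only.

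The counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr by group (16112 of 41543), libraries were scaled by TMM (factors 0.992 to 1.01), and groups were compared with the robust quasi-likelihood test, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors were derived from the fold change and its F statistic. The model held the group only. CPM values use the scaled library sizes. The common biological coefficient of variation was 0.112. Gene lists and chromosomes were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, and again with an estimated correlation, a correlation of 0.05 and fry. All 34 lists had at least 5 tested members. Positions and chromosomes came from GENCODE M21 on GRCm38, where 97.3% of the symbols were found. Transcript GC content was known for 98.4% of tested genes.

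The genes named in the text followed a rule written before the data were examined. It took Kat6a with its partners and paralogs, and Pou5f1, Sox2 and Nanog. Also named were the 10 largest rises and falls among called genes with at least 2-fold change and a mean of at least 1 CPM. These also needed KO and control libraries separated by group and a symbol that is not a predicted model. Each list gave up to 2 called members per direction, or the most abundant member where none was called. The 5 smallest adjusted p-values in each direction were taken among called genes under the condition on the symbol alone. The lists covered the KAT6A complex, chromatin regulators, pluripotency, the 2-cell-like state, embryonic and extraembryonic lineages, reported targets, germline and imprinted genes, cell growth, metabolism, stress and signalling, and markers of other cells. Some single genes and the senescence list are not reported here.

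Alternatives changed one choice at a time: RLE, upper quartile or no composition scaling, no low-count filter or a minimum of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, the likelihood ratio test, the replicate number as a block, a GC-content offset (lowess span 0.3 on transcript GC content), both together, and each library left out. With 1 library left out, the lone library of its group was assumed to vary like the other group. Alternatives without chromosome 11, without ribosomal, mitochondrial and small RNA genes, and without predicted models were added after seeing the data, as was the GC-content offset for lists and chromosomes. A planned comparison of promoters with and without CpG islands needs a genome sequence, which was not used here, and a comparison by first exons took its place in the closing section. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 prepared tables, intervals and plots.

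The procedure was tested on simulated data, with negative binomial counts drawn from the means, dispersions and library sizes of this comparison, of which 15861 genes passed the filter. The edgeR test recovered 12 of 66 genes changed by 0.5 on the log2 scale (18.2%), 41 of 67 changed by 1 (61.2%) and 57 of 65 changed by 2 (87.7%), all in the right direction. Of its 138 calls 28 were of unchanged genes, a share above the nominal 0.05. The simulation changed far fewer genes than the 2309 called in the data, and it gave both groups the same dispersion per gene. Its shares of recovered genes and false calls therefore hold for the simulated setting and are not rates for this comparison. Camera called a simulated list of 30 genes shifted by 0.6 and none of 20 unshifted lists, and it missed the shifted list with an estimated correlation.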

Results

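Messenger RNA was sequenced from E14TG2a cells, a mouse embryonic stem (ES) cell line grown in serum and the cytokine LIF on gelatin. Control cells were compared with cells in which KAT6A, a MYST-family histone acetyltransferase, had been knocked out (KO) by CRISPR/Cas9 genome editing. Each group had 2 libraries. The total counts were 35616899 and 37354623 in control replicates 1 and 2, and 30185640 and 27494041 in the libraries labelled KAT6A KO replicates 1 and 2. Of the 41543 gene symbols counted, 16112 were expressed highly enough to be tested, and these held 99.9% of all counts. The control libraries lay closer to each other than the KO libraries did. The SD over genes of the difference in log2 CPM (counts scaled to library size) was 0.26 between the controls and 0.46 between the KO libraries. Across genes, which are not independent replicates, Pearson's r was 0.996 within the controls, 0.988 within the KO libraries and 0.978 to 0.980 between the groups. The labels do not say whether the libraries of a group came from separate cultures or clones, so all p-values measure only the spread between these samples, which may be technical.

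Some properties of the libraries differed between or within the groups. Mitochondrially encoded genes held 2.24% and 2.25% of the counts in the controls, 1.80% in the library labelled KAT6A KO replicate 1 and 1.30% in the library labelled KAT6A KO replicate 2. The ribosomal RNA gene CT010467.1 held 0.862% of the counts in the library labelled KAT6A KO replicate 1 and between 0.308% and 0.353% in the other libraries. Fold changes also followed GC content. The median log2 fold change, KO over control, was -0.22 in the quintile of genes with the lowest transcript GC content (mean 41.3%) and 0.23 in the quintile with the highest (mean 58.9%). These medians ran from -0.11 to 0.14 in the library labelled KAT6A KO replicate 1 and from -0.34 to 0.30 in the library labelled KAT6A KO replicate 2, against -0.01 to 0.04 between the control libraries.

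The series asks what the loss of KAT6A does to gene expression in ES cells, and its title concerns the recruitment of KAT6A to unmethylated CpG islands. Kat6a RNA itself stood above the controls in one KO library and below them in the other. Kat6a is a protein-coding gene on chromosome 8, at 22859535 to 22943259 in GRCm38 with GENCODE M21. It had 145 and 143 CPM in the controls, 242 CPM in the library labelled KAT6A KO replicate 1 and 86.4 CPM in the library labelled KAT6A KO replicate 2, which are 1.69 and 0.601 times the control level. Over both libraries the log2 fold change was 0.19 ± 0.41 (SE), with an edgeR adjusted p of 0.772. Without the library labelled KAT6A KO replicate 1 it was -0.74, and without the library labelled KAT6A KO replicate 2 it was 0.75. The position of the edit is not given in the sources used here, and a count over the whole gene need not fall when a short edit shifts the reading frame, so these counts do not check the labels. Every direction given below rests on the labels as they stand.

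The gene of KAT6A's closest relative, Kat6b, and those of the scaffold partners Brpf1 and Brpf3 rose modestly, while the related scaffold gene Brd1 did not pass the test. Kat6b, the paralog that joins the same complex, went from 346 ± 5.48 CPM (SD, n = 2) to 510 ± 38.9 CPM (SD, n = 2), a log2 fold change of 0.56 ± 0.09 (SE) with an edgeR adjusted p of 0.016. Brpf3 rose by a log2 fold change of 0.53 and Brpf1 by 0.32. Of the JADE scaffolds, which pair with the related enzyme KAT7, Jade3 on the X chromosome fell, with a log2 fold change of -0.90, as did Jade2 on chromosome 11 (-0.79), while Jade1, the most abundant, did not pass (0.03). Brd1 (0.05), Ing5 (0.18), Meaf6 (0.33) and Kat7 on chromosome 11 (-0.16) did not pass the test. Without the library labelled KAT6A KO replicate 1 the log2 fold changes of Ing5, Meaf6 and Kat7 were 0.15, 0.20 and -0.17. Without the library labelled KAT6A KO replicate 2 they were 0.21, 0.45 and -0.16. Of the 12 tested members of the list of complex members and MYST enzymes, 3 rose and 2 fell, with the same counts adjusted over the list alone, and the list as a whole did not pass camera (adjusted p = 0.199). The rises of Kat6b, Brpf3 and Brpf1 were no longer called without control replicate 1 (edgeR adjusted p = 0.085, 0.20 and 0.44) or without control replicate 2 (edgeR adjusted p = 0.10, 0.077 and 0.46). The call of Jade2 ended without control replicate 2 (edgeR adjusted p = 0.13), and that of Brpf1 with a GC-content offset (edgeR adjusted p = 0.12) and with no low-count filter (edgeR adjusted p = 0.053).

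**Figure D1:**
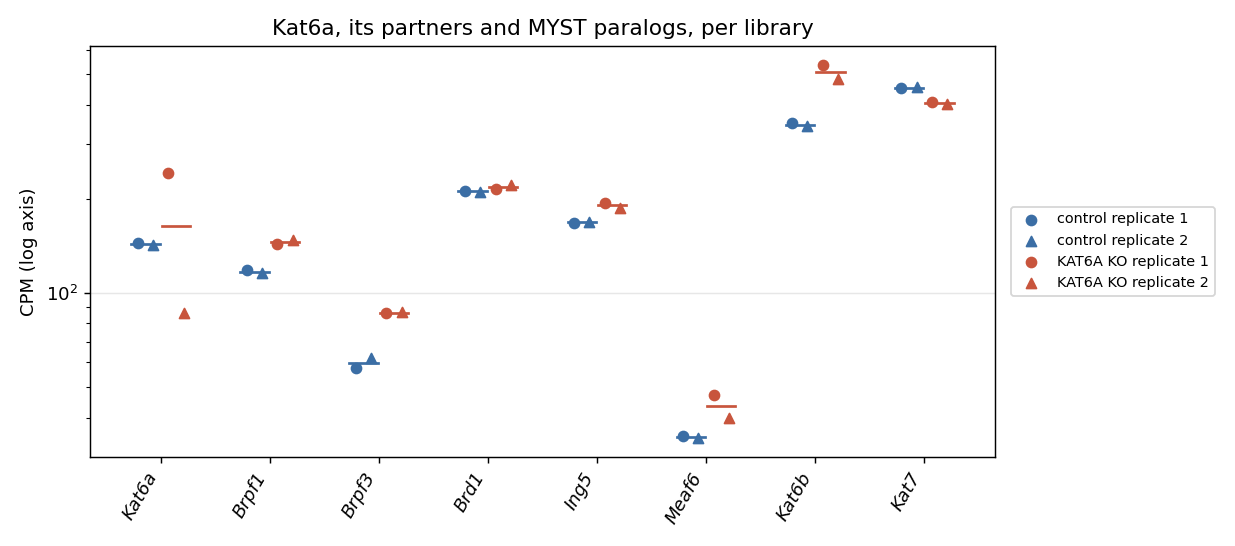
CPM on a log axis for Kat6a, its complex partners and MYST paralogs. Points are single libraries and bars are group means (n = 2). Kat6a lies at 242 and 86.4 CPM in the KO libraries, on either side of the controls, while both KO libraries lie above both controls for Kat6b, Brpf1 and Brpf3.

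Over all genes, 928 were higher and 1381 lower in the KO libraries at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), and 239 of the former and 414 of the latter changed at least 2-fold. These counts depended on single libraries. Without control replicate 1, 254 genes were higher and 670 lower, and without control replicate 2, 278 and 648. Without the library labelled KAT6A KO replicate 1, 4020 were higher and 4400 lower, and without the library labelled KAT6A KO replicate 2, 3532 and 3863, since the spread then came from the control pair alone.

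Chromosome 11 stood apart. Genes on this chromosome were lower along its whole length, by a median log2 fold change of -0.46, or 0.729 times the control level. Of its 1322 tested genes, 536 fell and 9 rose, and 88.6% had a fold change below 0. It held 38.8% of all genes called lower, against 8.21% of the genes tested. The median was -0.49 in the library labelled KAT6A KO replicate 1 and -0.42 in the library labelled KAT6A KO replicate 2, and -0.40 to -0.54 in 6 consecutive segments of the chromosome, against 0.00 between the control libraries. Camera placed chromosome 11 below the rest (adjusted p = 9.2e-31), and the adjusted p was 0.152 with an estimated correlation between genes. Without the genes of chromosome 11, an alternative chosen after seeing the data, 519 genes were higher and 697 lower. All named genes on this chromosome are marked as such below.

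Of the 22 chromosome sets, 7 passed camera. Chromosomes 7, 15 and 17 were higher, with medians of 0.15, 0.10 and 0.13, and chromosomes 11, 13, X and the mitochondrial genome were lower, with medians of -0.46, -0.17, -0.17 and -0.56. With an estimated correlation the adjusted p of these 7 sets lay between 0.152 and 0.487. With the GC-content offset, chosen here after seeing the data, chromosome 11 alone passed (adjusted p = 3e-43, median -0.51), and the other 6 did not. Chromosome 15 also lost its call without each library in turn (adjusted p from 0.066 to 0.36), chromosome 13 without the library labelled KAT6A KO replicate 1 (adjusted p = 0.13), and chromosomes 17 and X without the library labelled KAT6A KO replicate 2 (adjusted p = 0.085 and 0.11).

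**Figure D2:**
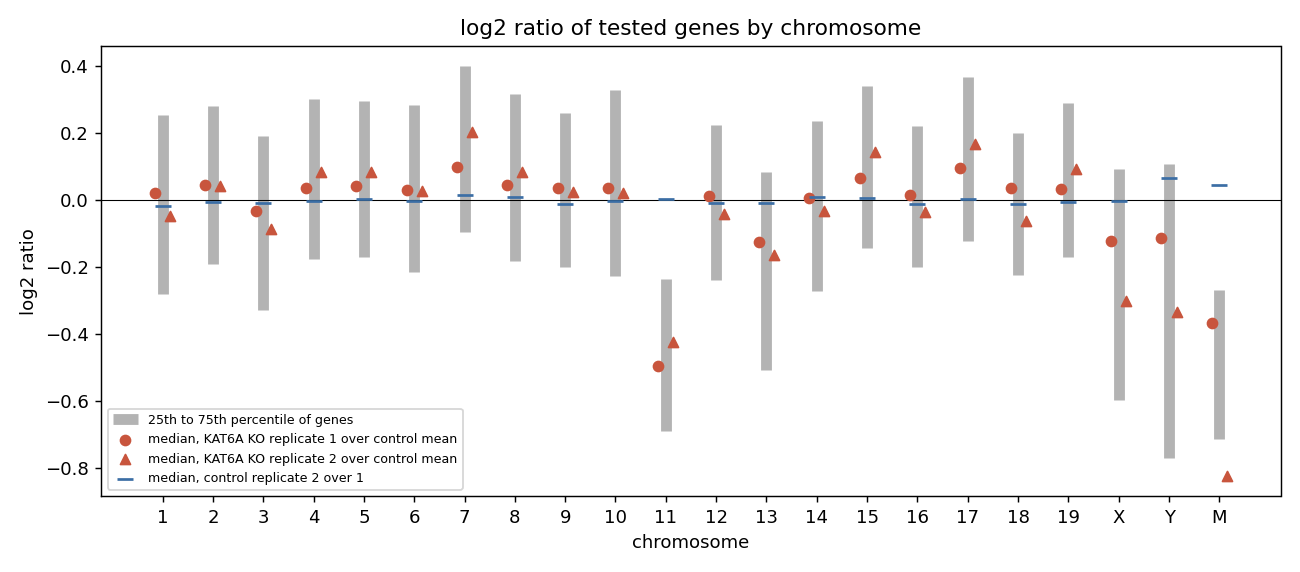
The log2 ratio of tested genes on each chromosome. Grey bars span the 25th to 75th percentile of the fitted log2 fold changes of single genes, red points are the median of each KO library over the control mean, and blue dashes are the median of control replicate 2 over replicate 1. On chromosome 11 the grey bar runs from -0.69 to -0.24 and lies wholly below 0.

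The largest falls included imprinted transcripts, developmental signalling genes and genes of extraembryonic lineages. Peg13, an imprinted noncoding RNA, had 101 and 123 counts in the controls and 1 and 3 in the KO libraries, a control level 44.7 times that of the KO cells with a 95% counting interval (exact binomial) of 17.2 to 165. H19, the imprinted noncoding RNA of the Igf2 locus, fell from 258 ± 1.88 CPM to 16.9 ± 8.88 CPM (SD, n = 2), which is 15.3-fold lower (log2 fold change -3.93 ± 0.33 SE, edgeR adjusted p = 0.0056). Nog, a BMP antagonist on chromosome 11, was 19.5-fold lower, and Bmp2, a BMP ligand, 7.65-fold lower. Thbd, which encodes thrombomodulin and marks parietal endoderm, was 15.5-fold lower at 0.493 and 2.04 CPM in the KO libraries. Nr4a3, a nuclear receptor, was 10.2-fold lower, Flrt2, a membrane adhesion protein, 9.95-fold, Mfsd2a, a lipid transporter, 8.16-fold, and Cxcl10, a chemokine, 8.07-fold. Hand1, a trophoblast and heart transcription factor on chromosome 11, was 8.87-fold lower. The smallest adjusted p-values among the falls belonged to Rhox5, an X-linked homeobox gene that went from 222 ± 3.97 to 55.1 ± 5.22 CPM (SD, n = 2), to Timp2 and Slc13a5 on chromosome 11 (4.81-fold and 3.94-fold lower), to Sfmbt2, an imprinted Polycomb-related gene (2.84-fold), and to Fosl2, an AP-1 subunit (3.82-fold), with edgeR adjusted p of 0.0038 to 0.0041. All of these calls held without each library in turn, but some folds did not. Without the library labelled KAT6A KO replicate 2 the log2 fold changes of Peg13, Nog, Thbd, H19 and Nr4a3 were -6.41, -4.99, -5.28, -4.60 and -4.01, and without the library labelled KAT6A KO replicate 1 those of Peg13 and Thbd were -4.77 and -3.24. With no low-count filter the calls of H19 and Thbd ended (edgeR adjusted p = 0.083 and 0.054). The call of H19 also ended with the replicate number as a block (edgeR adjusted p = 0.073).

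The largest rises were smaller in fold. Slc11a1, a metal ion transporter, rose 5.63-fold, to 28.0 and 12.5 CPM from 3.63 and 3.56 CPM. D1Pas1, an intronless relative of the RNA helicase gene Ddx3x, rose 4.86-fold from 12.6 ± 0.215 to 61.3 ± 14.3 CPM (SD, n = 2), with a log2 fold change of 2.28 ± 0.17 (SE) and an edgeR adjusted p of 0.0050. Zscan4c and Zscan4e, from the gene cluster that marks cells resembling the 2-cell embryo, rose 4.80-fold and 4.54-fold, Ubtfl1, a preimplantation gene, 4.41-fold, and Eif4a3l1 and Eif4a3l2, copies related to the helicase gene Eif4a3, 4.26-fold and 3.94-fold. Catip (4.57-fold), the cadherin gene Cdh22 (4.53-fold) and Vav1, an exchange factor of blood cells (3.71-fold), completed the 10 largest among genes with a mean of at least 1 CPM. Among the rises with the smallest adjusted p were Ifitm3, an interferon-induced membrane protein (2.66-fold), Apoe, a lipid carrier that went from 440 ± 23.2 to 963 ± 33.3 CPM (SD, n = 2), and Plcd1, a phospholipase (2.27-fold), with edgeR adjusted p of 0.0050 to 0.0061. Members of the Zscan4 cluster, D1Pas1 and the Eif4a3 copies share sequence with close relatives, so their separate counts are uncertain. All of these rises were called without each library in turn, but Slc11a1 was not with no low-count filter (edgeR adjusted p = 0.063). The log2 fold changes of Slc11a1 and Catip were 1.80 and 1.59 without the library labelled KAT6A KO replicate 1, and that of Vav1 was 1.28 without the library labelled KAT6A KO replicate 2.

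**Figure D3:**
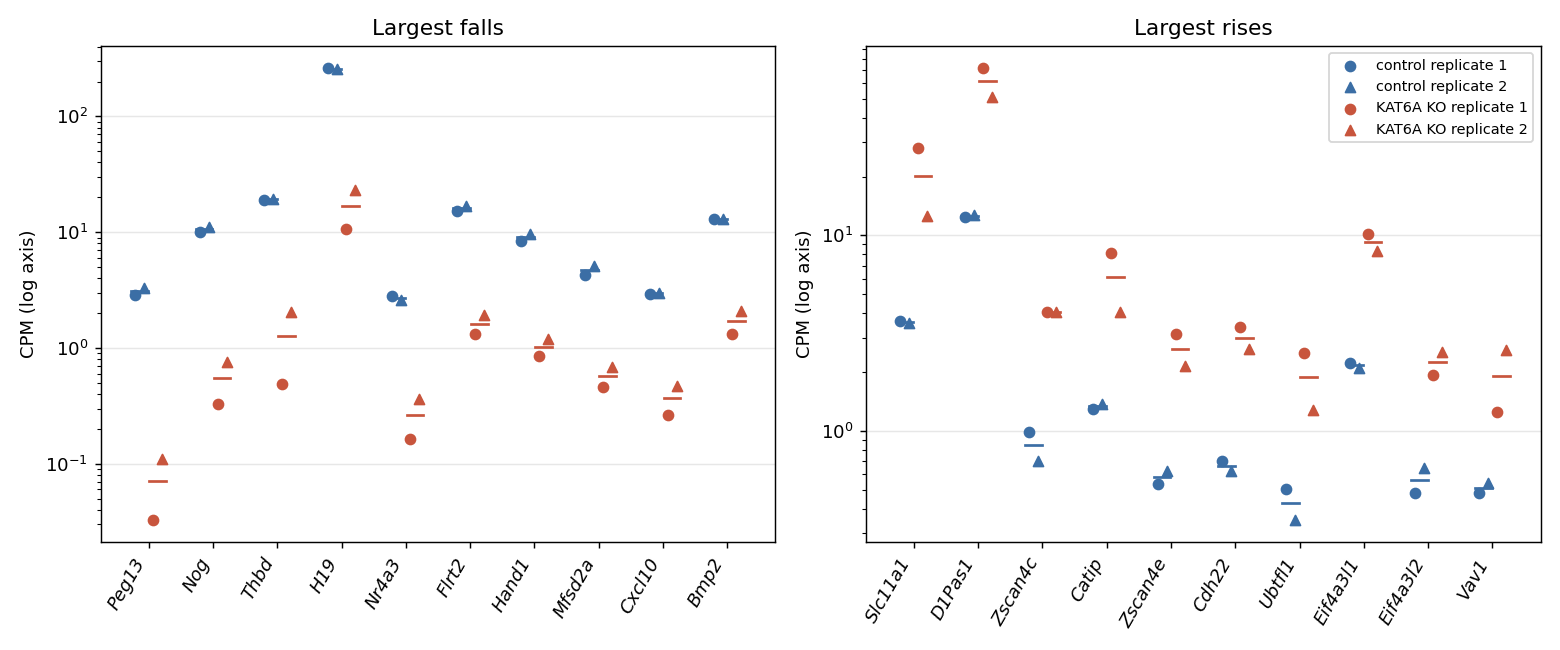
CPM on a log axis for the 10 largest falls and the 10 largest rises among called genes with a mean of at least 1 CPM and a symbol that is not a predicted model. Points are single libraries and bars are group means (n = 2). For H19 the controls lie at 259 and 257 CPM and the KO libraries at 10.6 and 23.2 CPM.

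Of 34 gene lists fixed before the data were examined, 7 passed camera at an adjusted p under 0.05, 3 of them higher and 4 lower in the KO libraries. None of the 34 was called with an estimated correlation, where the adjusted p was 0.699 for each of the 7 and no list had an unadjusted p under 0.05. Fry called 3 other lists, each at an adjusted p of 0.0304: the KAT6A complex list (higher), Polycomb genes (lower) and reported KAT6A targets (lower). Chromosome 11 holds 7 of the 29 Polycomb genes tested. The camera adjusted p of that list was 0.199 with them and 0.75 without the genes of chromosome 11. Fry was not run without that chromosome. Where a list had 5 or fewer called members they are named, and those outside the naming rule were chosen after their values were seen.

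Genes of the 2-cell-like state, a rare state of ES cells that express transcripts of the 2-cell embryo, rose together. Of 22 tested members 15 rose and none fell, or 17 and none adjusted over the list alone, with a median log2 fold change of 1.48 (camera adjusted p = 4e-08, and adjusted p = 0.699 with an estimated correlation). Pramef25 rose by a log2 fold change of 3.04 ± 0.36 (SE), from 0.179 to 1.49 CPM. Duxf3, a copy of the Dux transcription factor gene that switches on this state, rose by 2.35. Most of these genes were near the lower end of detection in the controls, and many belong to multicopy families whose reads the counting could split. The list median was 1.63 in the library labelled KAT6A KO replicate 1 and 1.27 in the library labelled KAT6A KO replicate 2, and the call held without each library in turn.

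Markers of definitive and primitive endoderm fell. Of 27 tested members 12 fell and 3 rose, or 18 and 4 adjusted over the list alone, with a median log2 fold change of -1.10 (camera adjusted p = 0.0011, and adjusted p = 0.699 with an estimated correlation). Besides Thbd, Fst, which encodes the activin antagonist follistatin, went from 33.2 ± 0.199 to 4.62 ± 1.80 CPM (SD, n = 2), 7.21-fold lower. The 3 that rose were Apoe, Amn, an endocytic receptor subunit of visceral endoderm (log2 fold change 1.09), and Hnf4a, a nuclear receptor of endoderm (1.04). The call of Hnf4a ended without either control (edgeR adjusted p = 0.074 and 0.072), and that of Amn without control replicate 1 (edgeR adjusted p = 0.13) and with the GC-content offset (edgeR adjusted p = 0.072), and narrowly with limma-voom or a minimum of 1 CPM (adjusted p = 0.051 and 0.052), and its log2 fold change was 0.69 without the library labelled KAT6A KO replicate 2. The list median was -1.73 in the library labelled KAT6A KO replicate 1 and -0.81 in the library labelled KAT6A KO replicate 2. Trophoblast markers fell as well. Of 23 tested members 10 fell and none rose, or 11 and none adjusted over the list alone, with a median of -0.70 (camera adjusted p = 3.1e-05, and adjusted p = 0.699 with an estimated correlation). Plac1, a placental gene on the X chromosome, had 39 and 54 counts in the controls and 2 and 1 in the KO libraries, a control level 24.7 times that of the KO cells with a 95% counting interval of 8.21 to 122. Hand1 was the other named member. The trophoblast medians of the libraries labelled KAT6A KO replicates 1 and 2 were -0.80 and -0.75, and both lists were called without each library in turn.

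Genes of cytosolic ribosomal proteins were higher as a group, by a median of 0.25. Of 53 tested members 6 rose and 3 fell, or 14 and 3 adjusted over the list alone (camera adjusted p = 1.7e-05, and adjusted p = 0.699 with an estimated correlation). Rps2 rose by a log2 fold change of 0.82 and Rps21 by 0.74, while Rps23 (-1.02), Rpl15 (-0.48) and Rpl23 on chromosome 11 (-0.35) fell. Ribosomal protein genes have many near-identical pseudogenes, so their single values are uncertain, and the calls of Rps23, Rpl15 and Rpl23 ended without either control (edgeR adjusted p from 0.087 to 0.44) and that of Rps2 with no low-count filter (edgeR adjusted p = 0.075). Without the library labelled KAT6A KO replicate 2 the log2 fold change of Rps2 was 0.49 and that of mt-Co1, given below, -0.48. The mitochondrially encoded genes were lower, as their share of the counts given above was smaller. Of 7 tested members 5 fell, with the same count adjusted over the list alone, and the median was -0.60 (camera adjusted p = 0.0032, and adjusted p = 0.699 with an estimated correlation). These were mt-Co1 (-0.74), mt-Nd1 (-0.64), mt-Nd2 (-0.62), mt-Nd5 (-0.60) and mt-Nd6 (-0.53), which encode subunits of respiratory complexes. The list medians were -0.41 in the library labelled KAT6A KO replicate 1 and -0.79 in the library labelled KAT6A KO replicate 2. With the GC-content offset this list was no longer called (adjusted p = 0.34), and mt-Nd1 lost its call with that offset (edgeR adjusted p = 0.059). Without control replicate 2, mt-Nd1, mt-Nd2, mt-Nd5 and mt-Nd6 were no longer called (edgeR adjusted p from 0.064 to 0.15), nor was mt-Nd6 without control replicate 1 (edgeR adjusted p = 0.063). The call of mt-Co1 ended with library size scaling, upper quartile scaling or a minimum of 1 CPM (edgeR adjusted p from 0.051 to 0.055).

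Cholesterol synthesis genes were lower by a small median of -0.16. Of 25 tested members 5 fell and none rose, or 7 and none adjusted over the list alone (camera adjusted p = 0.016, and adjusted p = 0.699 with an estimated correlation). Stard4, a sterol carrier, fell from 97.0 ± 3.28 to 58.4 ± 1.49 CPM (SD, n = 2), and the enzyme genes Cyp51 (log2 fold change -0.60), Sc5d (-0.53), Hmgcs1 (-0.41) and Msmo1 (-0.40) fell with it. The call of the list ended without control replicate 2 (adjusted p = 0.17) and without the library labelled KAT6A KO replicate 1 (adjusted p = 0.14), and that of Cyp51 without control replicate 2 (edgeR adjusted p = 0.12). Sc5d, Hmgcs1 and Msmo1 were not called without either control (edgeR adjusted p from 0.11 to 0.49). HOX genes, a class of KAT6A targets in the embryo, were higher as a list with a median of 0.81 over 14 tested members (camera adjusted p = 0.022, and adjusted p = 0.699 with an estimated correlation). Among them Hoxc13 alone rose, from 4.36 ± 0.634 to 9.79 ± 1.35 CPM (SD, n = 2), against 5 that rose and 1 that fell adjusted over the list alone. Fewer than 5 of the 14 members reached 1 CPM in at least 2 libraries, so the list could not be tested with that filter. Most of its values thus lay near the lower end of detection. The call of the list ended without the library labelled KAT6A KO replicate 1 (adjusted p = 0.26) and without the library labelled KAT6A KO replicate 2 (adjusted p = 0.060). It also ended without the genes of chromosome 11 (adjusted p = 0.055), and that of Hoxc13 without control replicate 2 (edgeR adjusted p = 0.053).

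**Figure D4:**
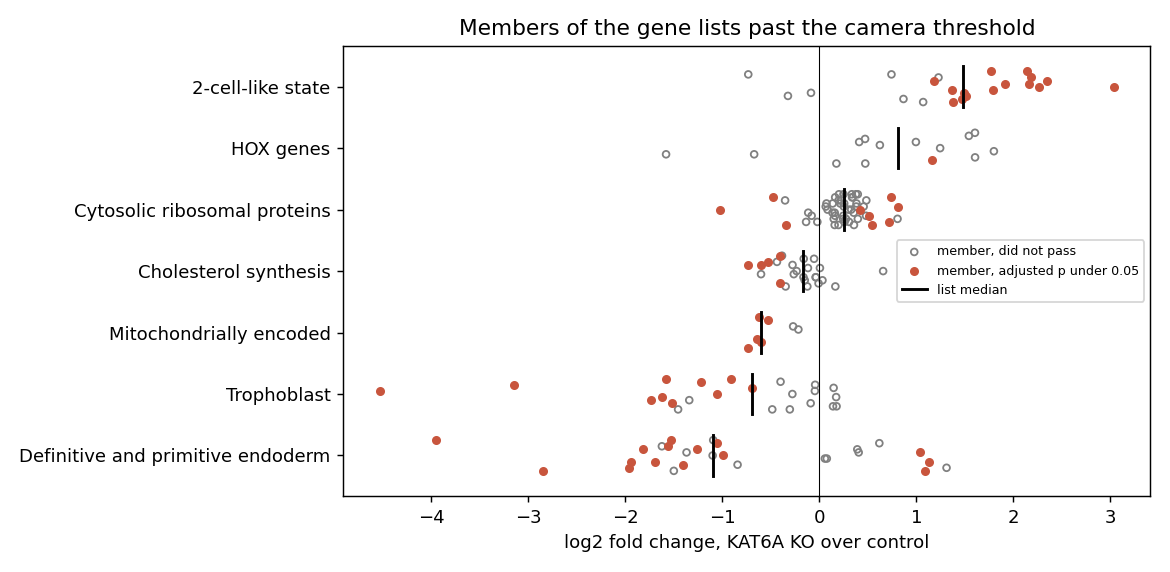
Fitted log2 fold changes, KAT6A KO over control, of the members of the 7 gene lists past the camera threshold. Filled points passed the test for single genes, open points did not, and black bars are list medians. The medians run from -1.10 for endoderm markers to 1.48 for genes of the 2-cell-like state.

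The remaining 27 lists did not pass camera with all libraries and no GC-content offset, with adjusted p between 0.053 and 0.92. Among them, naive pluripotency and WNT targets passed with the offset (adjusted p = 0.025 and 0.015) and without 3 of the 4 libraries in turn. Chromosome 11 holds 6 of the 20 WNT targets tested. Without the genes of that chromosome the camera adjusted p was 0.14 for WNT targets and 0.031 for naive pluripotency. Of the pluripotency genes, Pou5f1 had 616 ± 8.38 CPM in the controls and 881 ± 183 CPM in the KO libraries (SD, n = 2), a log2 fold change of 0.52 that missed the threshold (edgeR adjusted p = 0.059). It passed with DESeq2 (adjusted p = 0.0084), the edgeR likelihood ratio test (adjusted p = 0.0095) and no low-count filter (edgeR adjusted p = 0.027). It also passed with the replicate number as a block (edgeR adjusted p = 0.0046) and, narrowly, with upper quartile scaling (edgeR adjusted p = 0.0496). With the GC-content offset alone it did not pass. With block and offset together its log2 fold change was 0.32 (edgeR adjusted p = 0.041), against 0.50 with the block alone. In the authors' deposited table Pou5f1 passed as well (adjusted p = 0.0061). Its log2 fold change was 0.71 without the library labelled KAT6A KO replicate 1 and 0.28 without the library labelled KAT6A KO replicate 2. It did not pass without control replicate 1 or 2. Sox2, at a log2 fold change of 0.16, did not pass. It was 0.12 without the library labelled KAT6A KO replicate 1 and 0.20 without the library labelled KAT6A KO replicate 2. Nanog, at -0.07, did not pass. It was -0.20 without the library labelled KAT6A KO replicate 1 and 0.05 without the library labelled KAT6A KO replicate 2. In the core pluripotency list 1 of 17 tested members rose, Sall4 (0.50), with the same count adjusted over the list alone. In the naive pluripotency list 6 of 25 rose and 3 fell, or 7 and 3 adjusted over the list alone. Spp1 (0.76) and Dppa5a (0.61) were the largest rises, and the falls were Dppa3, a maternal-effect gene (-2.52), Stat3, the transducer of LIF signalling on chromosome 11 (-0.55), and the LIF receptor gene Lifr (-0.34). In the formative and primed list 1 of 19 rose, Etv5 (0.37), and none adjusted over the list alone; its median of 0.09 and its mean of -0.02 differed in sign. The calls of Sall4, Stat3, Lifr and Etv5 ended without either control (edgeR adjusted p from 0.067 to 0.47) and that of Dppa5a without control replicate 2 (edgeR adjusted p = 0.16).

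Among chromatin regulators, Suz12, a core Polycomb subunit on chromosome 11, fell from 857 ± 8.71 to 370 ± 52.8 CPM (SD, n = 2), a log2 fold change of -1.21. Of 29 Polycomb genes 4 rose and 6 fell, or 4 and 8 adjusted over the list alone. The rises were Aebp2 (0.62), Phc2 (0.42), Cbx7 (0.42) and Jarid2 (0.41). Of 19 CXXC and trithorax genes, which include other readers of CpG islands, 5 rose and none fell, with the same counts adjusted over the list alone: Wdr5 (0.58), Cxxc5 (0.44), Kmt2d (0.42), Tet1 (0.42) and Kmt2b (0.34). Of 16 other acetyltransferases and bromodomain readers Brd3 (0.48) and Brd2 (0.33) rose, or 1 adjusted over the list alone. The calls of Brd3, Brd2 and all of the named Polycomb and trithorax genes that rose ended without either control (edgeR adjusted p from 0.052 to 0.51), and those of Phc2, Cxxc5 and Brd2 with the GC-content offset (edgeR adjusted p from 0.074 to 0.33). Aebp2 was also not called with a minimum of 1 CPM (edgeR adjusted p = 0.055), and its log2 fold change was 0.36 without the library labelled KAT6A KO replicate 1.

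Of 18 tested genes reported as KAT6A targets outside HOX, 5 fell and none rose, or 6 and none adjusted over the list alone. Among them were Csf1r, a growth factor receptor of the myeloid lineage (-2.78), Meis1 on chromosome 11 (-1.16), Runx1 (-1.11) and Cdc6 on chromosome 11 (-0.60). In the imprinted list 4 of 41 fell and 1 rose, or 4 and none adjusted over the list alone. Besides Peg13 and H19 these were Grb10 on chromosome 11 (-1.54), Peg10 (-0.91) and, higher, Cd81 (0.31). Among germline genes silenced by promoter methylation 7 of 33 fell and 2 rose, or 12 and 4 adjusted over the list alone. Asz1 (-2.10) and Tuba3b (-1.26) fell most, and Rpl10l (0.96) and Mov10l1 (0.64) rose. Of 8 Y-chromosome genes Kdm5d fell (-1.72), with the same count adjusted over the list alone. Runx1 lost its call without control replicate 1 (edgeR adjusted p = 0.079), Tuba3b without control replicate 2 (edgeR adjusted p = 0.082), and Cd81, Mov10l1 and Meis1 without either control (edgeR adjusted p from 0.11 to 0.53). Cd81 also lost its call with the GC-content offset (edgeR adjusted p = 0.055) and with no low-count filter (edgeR adjusted p = 0.055). The log2 fold change of Csf1r was -3.43 without the library labelled KAT6A KO replicate 2, and those of Asz1 and Kdm5d were -2.94 and -2.38 without the library labelled KAT6A KO replicate 1.

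Markers of other lineages moved little as lists. Of 15 primitive streak genes Cdx1 rose (2.87), with the same count adjusted over the list alone, from 0.221 to 1.62 CPM, and its log2 fold change was 2.03 without the library labelled KAT6A KO replicate 1. Of 21 mesoderm, cardiac and blood genes Cdh5 (-1.80) and Runx1 fell, with the same count adjusted over the list alone. Of 21 neural genes 3 rose and 3 fell, with the same counts adjusted over the list alone: Sox1 (1.03), Neurod1 (0.84) and Tubb3 (0.65) were higher, and Irx3 (-1.27), Nes (-0.96) and Vim (-0.45) lower. Of 21 fibroblast markers Fn1 rose (0.41) and Col5a2 (-1.82), Ccn2 (-1.20), Ccn1 (-1.11) and Timp3 (-0.90) fell, or 3 and 4 adjusted over the list alone. Sox1, Neurod1, Irx3, Vim and Fn1 were no longer called without either control (edgeR adjusted p from 0.096 to 0.34), nor Runx1 and Tubb3 without control replicate 1 (edgeR adjusted p = 0.079 and 0.11), nor Sox1 with the GC-content offset (edgeR adjusted p = 0.065). Irx3 was also not called with DESeq2 (adjusted p = 0.17), nor, narrowly, with limma-voom (adjusted p = 0.051) or any of the 3 other scalings (edgeR adjusted p from 0.051 to 0.053).

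Signalling targets showed mostly single falls. Of 20 WNT targets 4 fell and 1 rose, or 6 and 2 adjusted over the list alone, namely Fst, Ccnd2, which encodes cyclin D2 (-2.18), Znrf3 (-0.68) and Tcf7 (-0.48), both on chromosome 11, and Cdx1. Of 19 TGF-beta, Nodal and BMP targets 4 fell and 1 rose, or 4 and 2 adjusted over the list alone, among them Id4 (-1.99), Id2 (-0.83), Grhl3 (-0.54) and, higher, Dusp9 (0.32). Of 23 FGF-ERK targets 3 fell and 1 rose, or 5 and 1 adjusted over the list alone: Phlda1 (-1.05), the immediate-early gene Egr1 (-0.68), Spred2 on chromosome 11 (-0.39) and Etv5. Of 28 stress-response genes 4 fell and 1 rose, or 6 and 1 adjusted over the list alone: Atf3 (-1.80), Xbp1 on chromosome 11 (-1.10), Dnajb9 (-0.62), Pdia4 (-0.47) and Atf4 (0.74). Of 22 interferon-stimulated genes 3 rose and 3 fell, or 3 and 5 adjusted over the list alone: Ifitm3, Isg20 (1.06), Ifitm1 (0.64), Irf1 on chromosome 11 (-0.81), B2m (-0.78) and H2-K1 (-0.60). Tcf7, Grhl3, Dusp9, Spred2, Etv5, Dnajb9, Pdia4, Isg20 and H2-K1 were no longer called without either control (edgeR adjusted p from 0.087 to 0.53), Znrf3 and Irf1 without control replicate 2 (edgeR adjusted p = 0.15 and 0.066), and Ifitm1 without control replicate 1 (edgeR adjusted p = 0.079). Dusp9 and Isg20 also lost their calls with the GC-content offset (edgeR adjusted p = 0.35 and 0.059). Atf3 was not called with DESeq2 (adjusted p = 0.055) or with no low-count filter (edgeR adjusted p = 0.33). Nor was it called with the replicate number as a block (edgeR adjusted p = 0.24), and its adjusted p in the authors' deposited table was 0.064. Its log2 fold change was -2.74 without the library labelled KAT6A KO replicate 2, and that of Cdx1 2.03 without the library labelled KAT6A KO replicate 1. Dusp9 was also not called with no low-count filter (edgeR adjusted p = 0.056) and Irf1 with a minimum of 1 CPM (edgeR adjusted p = 0.052).

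Growth and metabolism lists held few called members. Of 28 p53 targets 4 rose and 2 fell, or 5 and 2 adjusted over the list alone: Gdf15 (0.99), Phlda3 (0.52), Ei24 (0.37) and Bax (0.33) were higher, and Ccng1 on chromosome 11 (-0.74) and Btg2 (-0.48) lower. Of 40 DNA replication genes Mcm7 (0.64) and Mcm3 (0.43) rose and Ccne2 (-0.82), Cdc6 and Rpa1 on chromosome 11 (-0.33) fell, of 30 mitosis genes Cenpa (0.50) rose and Top2a (-0.55) and Birc5 (-0.46), both on chromosome 11, fell, and of 33 MYC and ribosome biogenesis genes Npm1 on chromosome 11 (-0.76) fell, all with the same counts adjusted over the list alone. Of 32 glycolysis and hypoxia genes Hk1 (0.48) rose and P4ha2 on chromosome 11 (-1.27) fell, with the same counts adjusted over the list alone, and the list median of 0.07 and mean of -0.03 differed in sign. None of the 12 tested genes of the histone list, which held the replication-independent H1f0 besides replication-dependent genes, passed edgeR or DESeq2, and 2 had an unadjusted edgeR p under 0.05. Only these 12 of the 47 listed members were counted highly enough to be tested, in libraries selected for polyadenylated RNA. The list medians were -0.52 and 0.05 in the libraries labelled KAT6A KO replicates 1 and 2. Phlda3, Ei24, Bax, Btg2, Mcm3, Rpa1, Cenpa, Top2a, Birc5 and Hk1 were no longer called without either control (edgeR adjusted p from 0.066 to 0.46), Gdf15 and Ccne2 without control replicate 2 (edgeR adjusted p = 0.14 and 0.088) and Mcm7 without control replicate 1 (edgeR adjusted p = 0.061). With the GC-content offset Gdf15, Phlda3, Ccne2 and Top2a were not called (edgeR adjusted p from 0.053 to 0.10), nor was P4ha2 with no low-count filter (edgeR adjusted p = 0.12).

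The authors' deposited table of the same comparison listed 1019 genes higher and 1482 lower at its adjusted p under 0.05. Of these 2501 genes, 2058 (82.3%) were called here in the same direction and none in the opposite one. With DESeq2, the authors' tool, 2468 (98.7%) were called here in the same direction. Across the 16112 tested genes, which are not independent replicates, the fold changes of the authors' deposited table and those computed here had a Pearson's r of 0.910 and a Spearman's rho of 0.979. In the authors' deposited table Kat6a had a log2 fold change of 0.08 and an adjusted p of 0.891. Among the shared genes the authors' folds were smaller, at a median of 0.925 times the log2 fold changes computed here, and far smaller for several of the largest falls. Peg13 had -2.23 in the authors' deposited table against -5.40 here, Plac1 -1.25 against -4.53, Thbd -0.93 against -3.95, H19 -1.95 against -3.93 and Nr4a3 -1.66 against -3.35.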

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

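The alternatives without chromosome 11 genes, without ribosomal, mitochondrial and small RNA genes and without predicted models, and the GC-content offset for lists and chromosomes, were chosen after seeing the data. With 2 libraries per group, single libraries set how many genes passed: over the 4 fits that left out 1 library, the count of higher genes ran from 254 to 4020, of lower genes from 648 to 4400, of genes at least 2-fold higher from 164 to 583 and at least 2-fold lower from 351 to 839. The estimate of spread came from the noisier KO pair when a control was left out and from the closer control pair when a KO library was. Kat6a ran from -0.74 to 0.75, with a reversed sign without the library labelled KAT6A KO replicate 1. The likelihood ratio test called 1666 higher and 2175 lower genes, 384 and 622 of them at least 2-fold. Without chromosome 11 genes, 519 were higher and 697 lower, all 1216 of them among the 1764 called off that chromosome; the cause was not tested. The other scalings, filters and tests kept these counts within 1.5 times.

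Of the 34 lists, 0 were called with an estimated correlation, 3 by fry, 5 with a correlation of 0.05, 11 to 14 when 1 library was left out and 14 with the GC-content offset. Among the 27 lists not called with all libraries, 8 passed with the GC-content offset: core and naive pluripotency, DNA replication, mitosis, the stress response, fibroblast markers, and WNT and FGF-ERK targets. Naive pluripotency, imprinted genes and WNT targets each passed in 3 of the 4 fits that left out 1 library, and naive pluripotency (adjusted p = 0.031) and Y-chromosome genes (adjusted p = 0.039) passed without chromosome 11 genes. Of 22 chromosome sets, 0 were called with an estimated correlation (4 had an unadjusted p under 0.05), 4 to 6 when 1 library was left out and 1 with the GC-content offset; the cause was not tested. At an adjusted p under 0.01, 174 genes were shared with the authors' deposited table, since edgeR then called 174 in all. With the replicate number as a block, 1613 genes were higher, 2147 lower and 12 lists called. The correlation of same-numbered deviations, from 2 pairs of libraries, was 0.095 across genes. The labels do not tie the numbers, but several lists differed in the same direction between replicates 2 and 1 of both groups. A condition shared by same-numbered libraries therefore stays open.

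Of 113 single genes reported, 56 kept direction and side of the threshold under all alternatives checked for single genes. The fit without chromosome 11 genes was not checked for single genes, and the counts below leave it out. That fit called 1216 of the 1764 genes called off that chromosome. Calls were lost for 33 without control replicate 1, 39 without control replicate 2, 14 with the GC-content offset and at most 10 under each other alternative. Signs reversed for genes close to 0: Brd1 to -0.0219 with the GC-content offset, with and without the block, and Nanog to 0.0252 with the offset and 0.0222 with offset and block. With 1 library left out Nanog ran from -0.203 without the library labelled KAT6A KO replicate 1 to 0.0537 without the library labelled KAT6A KO replicate 2. Versions of the CpG-island promoter comparison were not run, for want of a genome sequence. At a true change of 0.5 on the log2 scale the simulated test recovered 18.2% of genes, a share that holds for the simulated setting only. Transcripts with a few counts, such as Peg13 and Plac1, carry wide counting intervals.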

Other observations

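The tests of whether a KO library is a mislabelled control, the comparison of gene families and the comparison of first exons were chosen after results had been seen. Gene families were formed from shared symbols, and 5 of 246 families with at least 8 tested members passed camera; none was called with an estimated correlation (adjusted p = 0.963). Besides the Rps and Rpl ribosomal families, these were X-linked lymphocyte-regulated genes, serpins of clade B and keratins, all lower. Of 8 Xlr genes 5 fell, with a median log2 fold change of -1.66 (camera adjusted p = 0.0045), namely Xlr4a (-2.34), Xlr (-2.21), Xlr4b (-1.97), Xlr3a (-1.85) and Xlr5a (-1.46), of which Xlr was not called without either control (edgeR adjusted p = 0.075 and 0.070) and Xlr5a not without control replicate 2 (edgeR adjusted p = 0.085). The log2 fold changes of Xlr4b and Xlr5a were -3.32 and -2.11 without the library labelled KAT6A KO replicate 1, and that of Xlr4b -1.33 without the library labelled KAT6A KO replicate 2. Of 9 Serpinb genes 3 fell, with a median of -1.19 (camera adjusted p = 0.0083): Serpinb9 (-2.40), Serpinb6b (-2.30) and Serpinb9b (-1.91), protease inhibitors encoded together on chromosome 13. Of 20 keratins 6 fell and 1 rose, with a median of -0.83 (camera adjusted p = 0.048), among them Krt23 on chromosome 11 (-2.57) and Krt8 on chromosome 15 (-1.74). The call of Krt8 ended with the replicate number as a block (edgeR adjusted p = 0.23). Without the library labelled KAT6A KO replicate 2 the values of Serpinb9, Serpinb6b, Serpinb9b and Krt8 were -3.06, -2.95, -2.52 and -2.54. Chromosome 11 holds 12 of the 20 keratins and 3 of the 6 that fell, and the family was not tested without them. Members of the Xlr family share sequence, as do the Serpinb6 and Serpinb9 copies, so their separate counts are uncertain.

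The KO libraries also differed from each other on several lists, within and outside lineage markers. The endoderm list was higher in the library labelled KAT6A KO replicate 2 than in the library labelled KAT6A KO replicate 1 by a median of 0.89 on the log2 scale, above all 10000 random lists matched on expression. The mitochondrially encoded genes were lower by 0.44, and trophoblast and neural markers did not stand out. The germline list was lower by 0.42 and glycolysis genes higher by 0.43, where control replicate 2 also differed from replicate 1 in the same directions by 0.11 and 0.07. Core pluripotency, formative and primed pluripotency, WNT targets and cholesterol synthesis were also higher in replicate 2 of both groups. Their medians were 0.23, 0.34, 0.33 and 0.18 between the KO libraries and 0.08, 0.16, 0.11 and 0.14 between the controls. The endoderm, ribosomal protein and mitochondrially encoded lists moved in opposite directions in the 2 groups. These are descriptions of single libraries, and no test of the conditions.

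The lower RNA of chromosome 11 genes may reflect a lower dose of the whole chromosome in the KO cells than in the controls, as gain of this chromosome is a known change of cultured mouse ES cells. The highest median over 6 consecutive segments and both KO libraries was -0.337, so no segment was spared in either library, and the log2 ratio that 2 copies against 3 would give is -0.58. GC content does not account for it, since the median became -0.511 with the GC-content offset, and neither does a minority of regulated genes, since even the 75th percentile of the chromosome's genes was -0.236. Whether the dose differed in all cells or in part of them, and in the controls or the KO cells, stays open, as does a chromosome-wide effect of losing KAT6A, which the 2 groups cannot separate from a difference between the lines. Named genes such as Suz12, Nog and Hand1 fell further than the chromosome's median.

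Kat6a RNA went up in one KO library and down in the other, and mislabelling of either as a control is a possible explanation. Over genes called from the controls and the library labelled KAT6A KO replicate 2 alone, the library labelled KAT6A KO replicate 1 showed a median of 0.699 of the change, and in the reverse direction the median was 0.645. With changes measured from 1 control only and genes chosen without the other, the held-out control showed medians of 0.00 to 0.05 and the other KO library 0.637 to 0.760, which argues against both mislabellings. GC content does not account for the gap either, since the difference between the KO libraries was 1.46 on the log2 scale with the GC-content offset and 1.49 without. Different edits or clones behind the libraries, with different stability of the edited transcript, stay open and were not tested.

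The rise of 2-cell-like genes is a candidate effect of losing KAT6A. Reads shared within multicopy families do not account for all of it, since 2 of the 4 tested members outside such families, Zfp352 and Tmem92 (on chromosome 11), also rose, although the call of Zfp352 ended without control replicate 2 (edgeR adjusted p = 0.062). Nor does GC content, as the list median was 1.59 with the GC-content offset. A larger share of cells in this state, a higher level in each cell and a difference between the cell lines stay open, since these counts come from bulk RNA and the labels name no independent clones.

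As a hypothesis drawn from the series title, genes with CpG-rich first exons were expected to fall. Off chromosome 11, 8839 tested genes had a CpG-rich start of the first exon (first 500 bases, GC of at least 50% and a CpG observed/expected ratio of at least 0.6) and 3663 did not. The median log2 fold change of the CpG-rich class was lower by 0.05 (CpG-rich minus other, -0.0508), and camera did not separate the classes, so the data do not decide whether the classes differ. With the GC-content offset the difference was -0.0679; since the classes were not separated, neither value excludes a part played by GC content. Of the CpG-rich genes 5.93% were called higher, against 7.32% of the others, and 6.01% against 5.46% lower, with odds ratios of 0.543 and 0.935 within expression deciles. The plain shares called higher turned round without the library labelled KAT6A KO replicate 1 (29.0% against 20.7%) and without the library labelled KAT6A KO replicate 2 (23.9% against 20.8%), where the odds ratios within deciles were 0.762 and 0.744. Without control replicate 1 or 2 the shares were 1.10% against 2.82% and 1.34% against 2.78%, with odds ratios of 0.308 and 0.357; genes are not independent, so no p-value is attached.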
